A study of Mus musculus with 11 samples.

How the data were processed

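RNA sequencing of 11 skin tumours from C57BL/6 mice of a genetically engineered melanoma model was analysed, with the genotypes GNA11 Q209L (2 libraries), GNA11 Q209L Bap1 KO (5 libraries) and BRAF V600E Bap1 KO (4 libraries). GNA11 Q209L is a hotspot change of the G protein subunit alpha 11 found in uveal melanoma and blue naevi, BRAF V600E is the common activating change of cutaneous melanoma, and Bap1 is a nuclear deubiquitinase and tumour suppressor. The labels describe end-point tumours. They give no sex, litter, batch, date or tumour purity. Libraries were made from 1 ug of total RNA with a standard Illumina protocol, per the labels' protocols, which do not say whether strand was kept, so overlapping and antisense genes cannot be told apart.

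The authors deposited a single table of estimated counts per gene, with Ensembl gene IDs, mouse symbols and the 11 libraries as columns, and no normalisation. Alignment with STAR to mm9 is named in the submitters' processing notes, while the version, the counting program, the annotation and the handling of reads with several matches are not given in the sources used here. The gene values are whole numbers, so rounding the deposited expected counts changed nothing. The same columns also hold 3 measures of library quality, deposited per library: exon reads from 81 to 89, a 5' bias from 0.74 to 0.85 and a 3' bias from 0.58 to 0.62. They were kept out of the counts.

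Of the 18769 lines with an ID, 7 repeated another line with identical values and were dropped. The 6 transgene sequences were kept out of library sizes and gene tests and are described on their own. That left 18756 mouse genes, of which 17911 had their ID in the GENCODE table of gene names used here and 14 had no count in any library. Another 21 symbols had been turned into dates and were restored from their IDs, and 104 IDs share a symbol with another ID. For such a symbol the ID with the most counts was used. No genome of the build was used, so positions are not given. Total counts per library, rounded, ran from 18338100 to 81035100. A count of 3 corresponds to between 0.0337 and 0.166 CPM in a library (CPM is the count scaled to a common library size), and intervals and floors cover counting error alone.

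The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and the default expression filter by group, which kept 17350 genes. All 11 libraries were fitted together with genotype as the only term, so that the 3 genotypes share an estimate of the spread, because GNA11 Q209L has 2 libraries. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Log2 fold changes carry a standard error (SE) computed from the fold change and its F statistic. CPM values are TMM-scaled and given as mean ± SD over the libraries of a genotype. The prior degrees of freedom were 2.82 and the common dispersion 0.419. A gene with no count in a group has a fold given as a lower bound, the mean CPM of the other group over 3 counts pooled across that group. A gene with 1 to 3 counts has the same ratio to those counts, with the exact 95% Poisson interval of the counts. This definition of the ratio was chosen after the data were seen, in place of counts pooled over both groups.

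The named genes follow a rule: up to 12 genes with the largest rise and 12 with the largest fall in each of the 2 main comparisons, and 5 each way in the secondary one, among those past the threshold with an average log2 CPM of at least 2, groups that do not overlap and a symbol that is not a clone or predicted name. The rule allowed 5, 3594 and 2002 genes in the 3 comparisons. A set of 14 key genes, 1 of them not reported here, is given whatever its p-value, and up to 4 members of each list with the smallest p-values. The 29 gene lists cover melanocyte lineage and pigment, Gq and RasGRP signalling, MAPK pathway output, YAP and TEAD targets, neural crest and dedifferentiated melanoma, Schwann cell, epidermal keratinocyte, hair follicle, skeletal muscle, adipocyte, fibroblast and extracellular matrix, endothelial, macrophage and myeloid, neutrophil, mast cell, T and NK cell, B and plasma cell, red blood cell, antigen presentation, interferon response, proliferation, Hox genes, uveal melanoma class 2 high, uveal melanoma class 2 low, Bap1 complex partners, epithelial and mesenchymal switch, hypoxia and glycolysis, oxidative phosphorylation, and immediate early and heat shock genes. Of 531 list entries, 518 matched a gene of the table. Lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry stand beside it. Camera compares a list with all other genes, while fry asks whether its members move on balance in 1 direction. The grouping, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

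Libraries were compared before averaging. Within each genotype the smallest chi-square per degree of freedom between libraries was 87.5 or more, so no library was a repeat of another. The labels do not say which libraries come from separate mice, and 2 libraries of GNA11 Q209L Bap1 KO (replicates 1 and 2) share an identifier in their titles. P-values therefore measure the spread between these libraries. Replicate numbers were given here in accession order and pair nothing.

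The gene test was tested on counts simulated for the 17350 genes, with 200 genes changed in each of 3 runs. For GNA11 Q209L Bap1 KO against GNA11 Q209L it recovered 0.5% of the 2-fold, 15.4% of the 4-fold and 64.6% of the 16-fold changes, with 7 false calls among 167. For GNA11 Q209L Bap1 KO against BRAF V600E Bap1 KO these shares were 3.0%, 39.3% and 81.8%, with 13 false calls among 260, and for GNA11 Q209L against BRAF V600E Bap1 KO 0.5%, 12.4% and 60.1%, with 5 false calls among 150. In 1 simulated run, DESeq2 1.42.0 made 86 false calls among 186, 88 among 205 and 112 among 216 in these comparisons. The simulation gave each gene the same spread in all 3 genotypes. The real BRAF V600E Bap1 KO libraries varied more, with correlations from 0.762 to 0.931 against 0.940 to 0.961 in GNA11 Q209L Bap1 KO. Shares recovered and false calls may therefore differ in the real comparisons. A list shifted 2-fold was found in 3 of 3 runs by camera and by fry in each comparison, with 0 of 84 unchanged lists called, although simulated genes vary independently and real genes do not.

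The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (at least 1 CPM in 4 libraries), DESeq2, limma voom with sample quality weights, a fit of the 2 compared genotypes alone, summing the libraries that share an identifier, leaving out each library in turn, and asking for at least a 2-fold change. Chosen after the data were seen were a fit without the 619 tested genes on chromosomes X and Y, a covariate for libraries with Xist above 50 CPM, and fits without a pair of BRAF V600E Bap1 KO libraries. Transgene values were compared with exact two-sided permutation tests, adjusted over 18 tests. With 5 libraries against 2 the smallest p such a test can give is 0.095, with 5 against 4 it is 0.0159, and with 4 against 2 it is 0.133.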

Results

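Gene expression was measured by RNA sequencing in 11 end-point skin tumours of a mouse melanoma model on the C57BL/6 background. There were 2 tumours of the genotype GNA11 Q209L, 5 of GNA11 Q209L Bap1 KO and 4 of BRAF V600E Bap1 KO. Comparing GNA11 Q209L Bap1 KO with GNA11 Q209L asks what accompanies the Bap1 knockout under the same labelled oncogene. The level of the human GNA11-Q209L sequence differed between them (means of 11.9 and 74.1 CPM). Comparing GNA11 Q209L Bap1 KO with BRAF V600E Bap1 KO asks what differs between the oncogenes when both genotypes are labelled Bap1 KO. The comparison of GNA11 Q209L with BRAF V600E Bap1 KO differs in oncogene and in Bap1 together and isolates neither. The deposited counts, given here as rounded totals, summed to 42180300 and 25792400 per library in GNA11 Q209L. They summed to about 18338100, 22584700, 19400100, 20987400 and 69712200 in GNA11 Q209L Bap1 KO, and to about 81035100, 21539600, 21974300 and 22579000 in BRAF V600E Bap1 KO.

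Tumours with GNA11 Q209L were full of pigment cell transcripts, with or without the label Bap1 KO. The BRAF V600E Bap1 KO tumours had few of them and differed widely from one another. The 22 genes of melanocyte lineage and pigment averaged 9.63 to 9.95 log2 CPM in each of the 7 libraries with GNA11 Q209L. They averaged 1.61, 2.41, 3.33 and 3.81 in BRAF V600E Bap1 KO replicates 1 to 4. Principal component 1 held 51.4% of the variance. On it the libraries with GNA11 Q209L lay between -130.9 and -35.3 and the BRAF V600E Bap1 KO libraries between 106.4 and 203.1. Component 2 held 16.7% and parted BRAF V600E Bap1 KO replicates 1 and 2 (-145.8 and -109.3) from replicates 3 and 4 (75.2 and 116.2). Pearson's r between libraries was taken across genes, which are not independent replicates. It ran from 0.940 to 0.961 over the 10 pairs of GNA11 Q209L Bap1 KO, was 0.937 for the GNA11 Q209L pair, and ran from 0.762 to 0.931 over the 6 pairs of BRAF V600E Bap1 KO. Between the libraries with GNA11 Q209L and those with BRAF V600E it ran from 0.687 to 0.826 over 28 pairs. The 10 most abundant genes took 21.9% of the counts in BRAF V600E Bap1 KO replicate 4. There Bpifa2, a secreted protein of the salivary gland, alone took 9.93%.

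**Figure D1:**
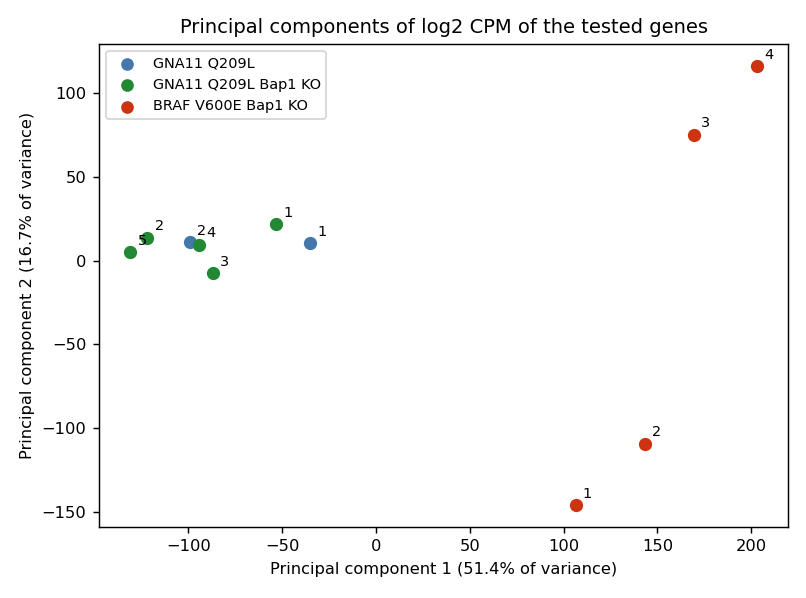
Principal components 1 and 2 of log2 CPM, with the share of variance in percent on each axis; each point is a library, coloured by genotype and numbered by replicate. The 4 BRAF V600E Bap1 KO libraries lie above 106 on component 1 and split along component 2.

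The deposited table also counts 6 transgene sequences. The human GNA11-Q209L sequence stood at 74.1 CPM in GNA11 Q209L (23.0 and 125) and at 11.9 ± 5.40 CPM (SD, n = 5) in GNA11 Q209L Bap1 KO. In BRAF V600E Bap1 KO it stood at 0.0226 ± 0.0276 CPM (SD, n = 4), and at 0.0114 CPM without its replicate 1. The nuclear EGFP sequence behind an internal ribosome entry site followed the same order, with means of 48.1 (21.1 and 75.1), 6.63 and 0.0456 CPM, the last being 0.0259 CPM without BRAF V600E Bap1 KO replicate 3. The human BRAF exon 15-18 sequence stood at 1.83 ± 0.823 CPM in BRAF V600E Bap1 KO. It had 0 counts in GNA11 Q209L and 1 in all of GNA11 Q209L Bap1 KO. CreERT2, the tamoxifen-dependent recombinase, averaged 251 ± 51.9 CPM in GNA11 Q209L Bap1 KO, 108 CPM in GNA11 Q209L and 6.49 ± 12.1 CPM in BRAF V600E Bap1 KO. The last mean rests on BRAF V600E Bap1 KO replicate 3 (24.7 CPM) and was 0.43 CPM without it. The FLP recombinase ran from 0.0541 to 154 CPM in GNA11 Q209L Bap1 KO and from 0.418 to 174 CPM in BRAF V600E Bap1 KO, with a mean of 0.0354 CPM in GNA11 Q209L. The neomycin resistance sequence averaged 5.12 CPM in GNA11 Q209L, 3.03 CPM in GNA11 Q209L Bap1 KO and 12.05 CPM in BRAF V600E Bap1 KO. Between BRAF V600E Bap1 KO and GNA11 Q209L Bap1 KO the groups did not overlap for any of these but the FLP recombinase. The exact two-sided permutation p was 0.0159 for each (0.0572 adjusted over 18 tests) and 0.714 for the FLP recombinase. Against GNA11 Q209L, the human GNA11-Q209L sequence, EGFP and CreERT2 reached exact p = 0.0952, the smallest that 5 against 2 libraries allow. No order can be read for the FLP recombinase there, since GNA11 Q209L Bap1 KO replicate 3 and both GNA11 Q209L libraries had 1 count each. The neomycin sequence had exact p = 0.381 there.

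**Figure D2:**
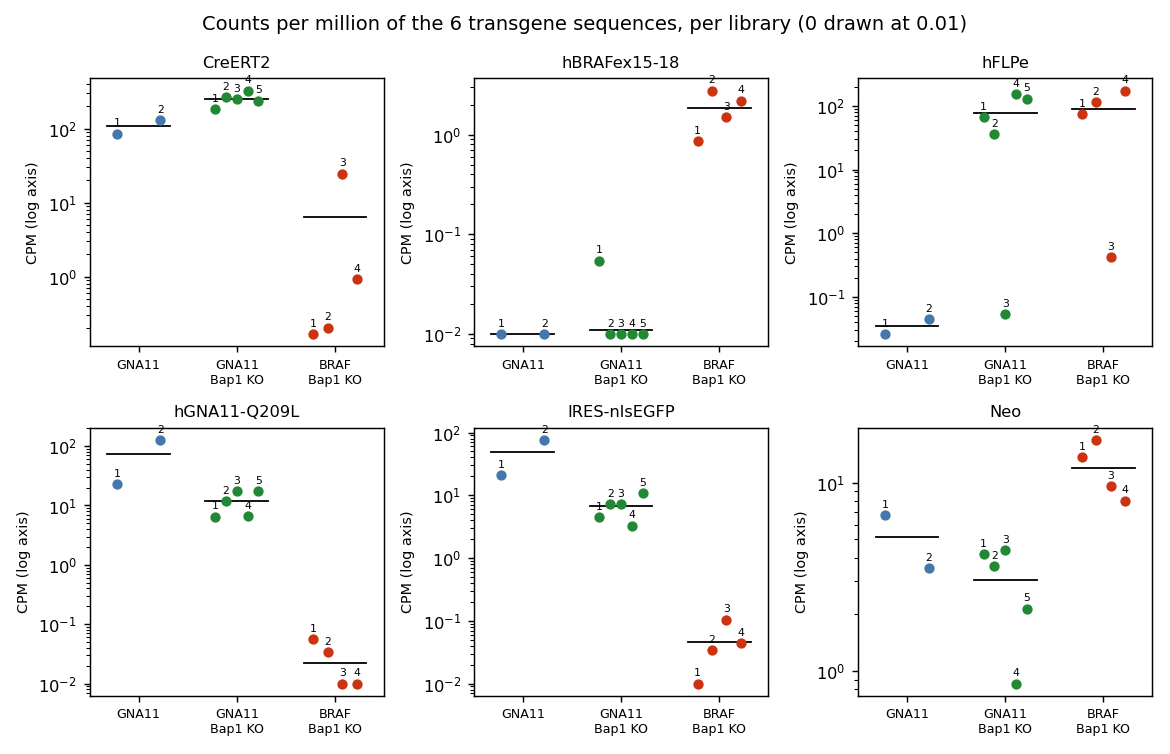
CPM on a log axis of the 6 transgene sequences in each library, coloured by genotype, with the mean as a black line and values of 0 drawn at 0.01. The human GNA11-Q209L sequence is above 6 CPM in every library with GNA11 Q209L and under 0.06 CPM in the BRAF V600E Bap1 KO libraries.

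Few single genes passed the test between tumours labelled GNA11 Q209L Bap1 KO and GNA11 Q209L. Scube1 (ENSMUSG00000016763), a secreted and cell-surface protein with EGF-like repeats, was 42.4-fold higher in GNA11 Q209L Bap1 KO. It stood at 49.1 ± 22.4 CPM (SD, n = 5) against 1.16 ± 0.0056 CPM (SD, n = 2), a log2 fold change of 5.40 ± 0.63 (SE, adjusted p = 0.0217). Dpysl3 (ENSMUSG00000024501), a cytoskeletal regulator of growing neurites, was 13.4-fold lower, at 14.1 ± 5.39 against 188 ± 93.2 CPM (log2 -3.75 ± 0.43, adjusted p = 0.0217). Its GNA11 Q209L mean was 122 CPM without GNA11 Q209L replicate 2. Maoa (ENSMUSG00000025037), the monoamine oxidase A of mitochondria, was 6.56-fold lower, at 10.4 ± 1.89 against 68.4 ± 28.5 CPM (log2 -2.71 ± 0.31, adjusted p = 0.0217). Fbxo32 (ENSMUSG00000022358), a ubiquitin ligase subunit best known from muscle wasting, was 8.19-fold lower (16.7 ± 5.08 against 137 ± 43.6 CPM, adjusted p = 0.0489). Pid1 (ENSMUSG00000045658), an adaptor protein that binds phosphorylated tyrosine, was 3.61-fold lower (10.4 ± 0.58 against 37.6 ± 1.44 CPM, adjusted p = 0.0489). These 5 genes, 1 higher and 4 lower, are all that passed among 17350 with edgeR fitted to all 11 libraries, with 1970 genes at an unadjusted p under 0.05. Fitted to the 2 genotypes alone, edgeR called 64 genes. It called 0 with the libraries that share an identifier summed, and 0 with a covariate for the Xist level. DESeq2 called 442 genes and limma voom 16. In 2878 genes (16.6%, where chance gives 9.52%) the groups did not overlap. Leaving out GNA11 Q209L Bap1 KO replicate 4 left Scube1 alone past the threshold, and leaving out replicate 5 left Dpysl3 alone. Without any other library of the 2 genotypes the count was 0 with edgeR, with 945 to 1972 genes at an unadjusted p under 0.05. Xist, the RNA of the inactive X chromosome, was above 50 CPM in both GNA11 Q209L libraries and in 1 of the 5 GNA11 Q209L Bap1 KO libraries (replicate 3, 695 CPM).

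**Figure D3:**
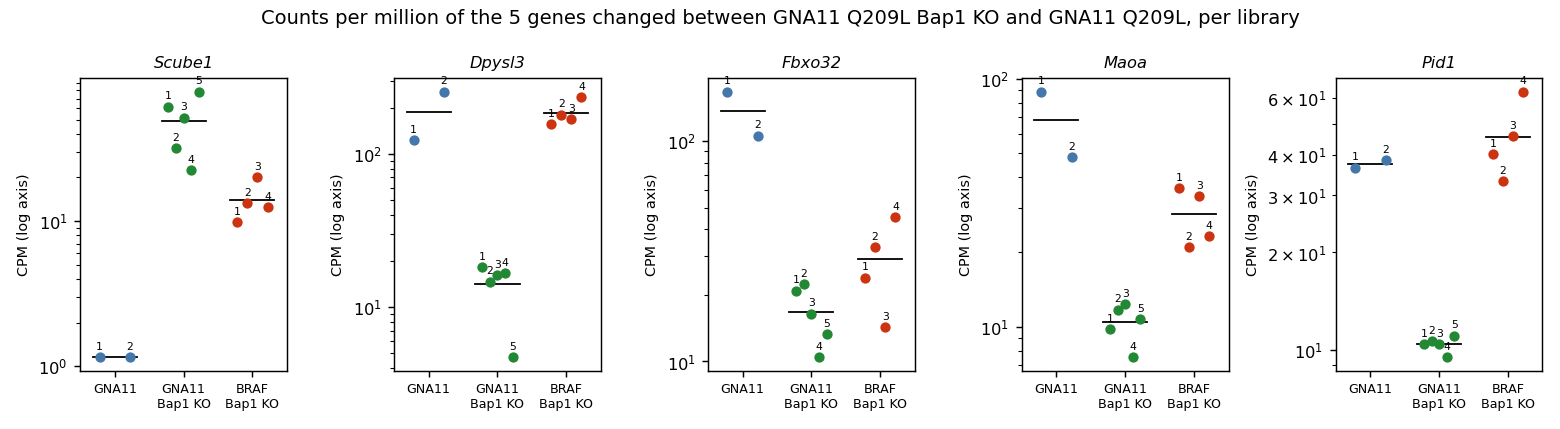
CPM on a log axis of the 5 genes past the threshold between GNA11 Q209L Bap1 KO and GNA11 Q209L, in each library, with the mean of each genotype as a black line. Scube1 lies near 1.16 CPM in both GNA11 Q209L libraries and averages 49.1 CPM in GNA11 Q209L Bap1 KO.

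The key genes given here, chosen for their place in these tumours, did not pass between GNA11 Q209L Bap1 KO and GNA11 Q209L. The gene-level count of Bap1 itself was 121 ± 29.7 CPM in GNA11 Q209L Bap1 KO and 111 ± 36.8 CPM in GNA11 Q209L (adjusted p = 0.92). This count does not show the labelled knockout, and the exons removed are not given in the sources used here. Rasgrp3, an exchange factor that links Gq signalling to Ras, stood at 643 ± 271 against 168 ± 52.6 CPM (log2 fold change 1.93 ± 0.64, adjusted p = 0.309). Plcb4, a phospholipase downstream of Gq, stood at 255 ± 124 against 20.3 ± 9.04 CPM (3.65 ± 1.21, adjusted p = 0.312). Mitf, the master regulator of melanocytes, stood at 719 ± 322 against 338 ± 9.15 CPM (adjusted p = 0.399). Its pigment targets Tyr (2633 ± 901 against 1481 ± 250 CPM, adjusted p = 0.728) and Dct (27600 ± 6399 against 22520 ± 4718 CPM, adjusted p = 0.935) were high in both genotypes. The receptor gene Kit stood at 92.0 ± 106 against 186 ± 8.30 CPM (adjusted p = 0.738), and the kinase genes Prkcd at 56.7 ± 9.03 against 111 ± 92.3 CPM (adjusted p = 0.407) and Braf at 44.8 ± 13.6 against 39.3 ± 9.78 CPM (adjusted p = 0.892). The G protein genes Gna11 (320 ± 132 against 290 ± 215 CPM, adjusted p = 0.958) and Gnaq (131 ± 18.5 against 90.1 ± 5.64 CPM, adjusted p = 0.382) did not pass either. Cdkn2a (15.2 ± 7.31 against 39.7 ± 10.4 CPM, adjusted p = 0.755) and Trp53 (104 ± 20.3 against 62.8 ± 0.994 CPM, adjusted p = 0.495), which restrain the cell cycle, did not pass. In GNA11 Q209L replicate 1 and 2 Prkcd stood at 176 and 45.2 CPM and Gna11 at 138 and 442 CPM. The Kit mean of GNA11 Q209L Bap1 KO was 46.0 CPM without its replicate 3.

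Proliferation genes stood higher in GNA11 Q209L Bap1 KO than in GNA11 Q209L as a list. Of its 26 genes 0 passed over all genes, but 23 were higher when adjusted over the list alone. Their median log2 fold change was 1.63 (camera adjusted p = 2.38e-22, adjusted p = 0.51 with an estimated correlation). With a covariate for the Xist level it was 0.97. Mki67, a marker of cycling cells, stood at 74.9 ± 69.5 against 8.39 ± 0.318 CPM (log2 fold change 3.16 ± 0.80, adjusted p = 0.221), the former being 44.8 CPM without GNA11 Q209L Bap1 KO replicate 1. Top2a, which untangles DNA, stood at 71.1 ± 33.1 against 12.8 ± 1.47 CPM (2.47 ± 0.51, adjusted p = 0.133) and the spindle motor Kif11 at 19.5 ± 10.9 against 3.36 ± 0.209 CPM (2.53 ± 0.63, adjusted p = 0.213). The proliferation mean was 3.10 and 3.85 log2 CPM in GNA11 Q209L and from 4.08 to 5.57 in GNA11 Q209L Bap1 KO. The lowest of the latter was that of replicate 3, the library high in Xist. The 20 Bap1 complex partners also stood higher, with a median of 0.44 (camera adjusted p = 0.00953, adjusted p = 0.51 with an estimated correlation). None of them was called over all genes or adjusted over the list alone, and the methyltransferase Ezh2 stood at 36.0 ± 11.7 against 16.3 ± 5.65 CPM (adjusted p = 0.354).

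In GNA11 Q209L Bap1 KO 7 lists stood lower than in GNA11 Q209L, with 0 members called over all genes in any of them. The 18 fibroblast and extracellular matrix genes had a median log2 fold change of -2.31 (camera adjusted p = 1.24e-07, adjusted p = 0.51 with an estimated correlation). Of these genes 7 were lower when adjusted over the list alone. The collagen-binding proteoglycan Dcn stood at 25.7 ± 17.8 against 414 ± 327 CPM (-4.01 ± 0.80, adjusted p = 0.131), with 645 and 182 CPM in GNA11 Q209L replicate 1 and 2. The 26 Hox genes, which set position along the body, had a median of -1.96 (camera adjusted p = 3.03e-07, adjusted p = 0.555 with an estimated correlation). The 18 macrophage and myeloid genes had a median of -1.86 (camera adjusted p = 6.83e-05, adjusted p = 0.652 with an estimated correlation), with the lysozyme gene Lyz2 at 230 ± 174 against 2021 ± 2578 CPM (adjusted p = 0.258), and at 3840 and 198 CPM in GNA11 Q209L replicate 1 and 2. Endothelial genes had a median of -0.70 (camera adjusted p = 0.00953, adjusted p = 0.652 with an estimated correlation). Their only member lower when adjusted over the list alone was Vwf, a carrier of a clotting factor. Interferon response genes had a median of -0.62 (camera adjusted p = 0.0244), red blood cell genes -1.67 (0.0365) and antigen presentation genes -0.95 (0.0365). Each of these 3 had adjusted p = 0.786 with an estimated correlation. The Hox, macrophage, interferon, red blood cell and antigen presentation lists had 0 members lower or higher when adjusted over the list alone.

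These calls rest largely on GNA11 Q209L replicate 1. Without it the fibroblast median was -1.04 and still called. The Hox median was -0.61 and not called (adjusted p = 0.0923). Medians of macrophage (0.16), endothelial (-0.03), red blood cell (0.35), antigen presentation (0.27) and interferon genes (0.18) were not called either. Without GNA11 Q209L replicate 2 the endothelial, antigen presentation and interferon medians were -1.09, -1.53 and -1.04. Red blood cell genes were also not called without GNA11 Q209L Bap1 KO replicate 1 (adjusted p = 0.069), 3 (0.0995) or 4 (0.0875), and had a median of -2.61 without replicate 5. Antigen presentation genes were not called without replicate 4 (0.092) or 5 (0.143), nor interferon genes without replicate 5 (0.196, median -0.37).

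The other 20 lists did not pass between GNA11 Q209L Bap1 KO and GNA11 Q209L. Melanocyte lineage and pigment genes had a median of 0.32 (camera adjusted p = 0.417). The endothelin receptor gene Ednrb was their only member lower when adjusted over the list alone, at 23.3 ± 2.17 against 234 ± 249 CPM (adjusted p = 0.174 over all genes). The latter mean rests on GNA11 Q209L replicate 1, with 410 CPM against 57.7 CPM in replicate 2. YAP and TEAD targets had a median of -0.23 (camera adjusted p = 0.242), and the receptor kinase Axl and the RNA-binding protein Rbms3 were lower when adjusted over the list alone. Signalling lists lay near 0, with medians of -0.07 for Gq and RasGRP signalling, 0.33 for MAPK pathway output and 0.01 for immediate early and heat shock genes, whose mean was negative. Medians were -0.24 for oxidative phosphorylation, -0.71 and -0.12 for uveal melanoma class 2 high and low genes and -0.86 for the epithelial and mesenchymal switch. They were -0.15 for neural crest and dedifferentiated melanoma and -0.79 for Schwann cells. Epidermal keratinocyte genes had a median of 4.67, or 4.43 with genes at no count set to their bound (camera adjusted p = 0.0927). They averaged 4.65 log2 CPM in GNA11 Q209L Bap1 KO replicate 1 against -2.56 to -0.84 in its other libraries. Skeletal muscle genes had a median of 2.07, adipocyte -1.39, mast cell -0.07, T and NK cell -0.94 and B and plasma cell genes -0.86. Neutrophil genes had -0.15 with a positive mean, and hair follicle genes -0.29, or -1.01 with genes at no count set to their bound. Hypoxia and glycolysis genes had -0.36 and were called in opposite directions without GNA11 Q209L replicate 1 (-0.92, adjusted p = 3.41e-05) and without replicate 2 (0.90, adjusted p = 0.0148). Without GNA11 Q209L replicate 2 there were also calls for MAPK output (adjusted p = 0.000657), adipocyte (0.00586), T and NK cell (1.52e-06) and B and plasma cell genes (0.0148). Leaving out GNA11 Q209L Bap1 KO replicate 1 gave a call for neural crest genes (0.0465), and leaving out replicate 2 for oxidative phosphorylation (0.00822). Keratinocyte genes were called without replicate 3 (0.0422), 4 (0.0401) or 5 (0.00986), and muscle genes without replicate 5 (0.0395).

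Between the genotypes labelled Bap1 KO, the largest rises in GNA11 Q209L Bap1 KO included those of pigment cell genes. Pmel, which builds the fibrils of the melanosome, reached 33220 ± 13320 CPM (SD, n = 5) in GNA11 Q209L Bap1 KO against 17.8 ± 9.75 CPM (SD, n = 4) in BRAF V600E Bap1 KO. Its log2 fold change was 10.86 ± 0.99 (SE, adjusted p = 0.000142). Among the melanin enzymes, Tyrp1 stood at 20520 ± 7936 against 20.3 ± 13.7 CPM (log2 9.98 ± 0.92), Dct at 27600 ± 6399 against 26.4 ± 20.1 CPM (10.03 ± 0.96) and Tyr at 2633 ± 901 against 4.84 ± 4.30 CPM (9.09 ± 0.83). The melanosome transporters Slc45a2 (2852 ± 716 against 2.80 ± 2.11 CPM) and Oca2 (978 ± 124 against 1.38 ± 0.968 CPM, 9.49 ± 0.64) were also higher. Adjusted p-values of these 5 genes ran from 3.35e-05 to 0.000183. Further genes with the largest rises were the melanocyte coactivator Cited1 (1760 ± 1073 against 0.639 ± 0.415 CPM, 11.43 ± 0.90) and the potassium channel Kcnj13 (409 ± 182 against 0.15 ± 0.152 CPM, 11.42 ± 0.83). The neuropeptide Cort (106 ± 68.2 against 0.0401 ± 0.0345 CPM, 11.33 ± 0.80) and the tetraspanin Tspan10 (958 ± 374 against 0.682 ± 0.314 CPM, 10.48 ± 0.64) followed. Dcdc2a (17.1 ± 17.2 against 0.0275 ± 0.0413 CPM, 9.25 ± 1.72, adjusted p = 0.00323) and Eif2c5 (22.2 ± 2.496 against 0.048 ± 0.0558 CPM, 9.04 ± 0.92, adjusted p = 0.000234) complete the 12. Some BRAF V600E Bap1 KO means rest on single libraries: without replicate 4 they were 2.90 CPM for Tyr, 1.83 CPM for Slc45a2 and 0.00749 CPM for Dcdc2a, without replicate 2 0.0756 CPM for Kcnj13, and without replicate 3 0.0291 CPM for Eif2c5. Dcdc2a was not called with limma voom (6.95, adjusted p = 0.178, the highest over its alternatives, where the lowest was 7.08e-11).

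In this comparison 7146 of 17350 genes passed, 2865 of them higher and 4281 lower in GNA11 Q209L Bap1 KO. Counts of list members past the threshold are to be read beside these shares. At least a 2-fold change was found in 6191 of them. The groups did not overlap in 5524 genes (31.8%, where chance gives 1.59%), among them 5041 of those that passed. The median log2 fold change of all genes was -0.262.

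The genes furthest below in GNA11 Q209L Bap1 KO include several of the skin surface. Crnn, a cornified envelope protein with no count there, was at least 1940-fold lower (BRAF V600E Bap1 KO 43.5 ± 86.2 CPM, adjusted p = 0.0396). The bound was 19.2-fold without BRAF V600E Bap1 KO replicate 4 and 1100-fold without GNA11 Q209L Bap1 KO replicate 5. Crnn was not called when any single GNA11 Q209L Bap1 KO library was left out (adjusted p = 0.0569 to 0.067) or with the libraries that share an identifier summed (0.0592). The antiprotease Wfdc12 had 0.0543 ± 0.121 against 309 ± 610 CPM (log2 -12.72 ± 2.76, adjusted p = 0.00618). Its change was -6.13 when BRAF V600E Bap1 KO replicate 4 was left out, and it was not called with limma voom (-8.64, adjusted p = 0.067, where its alternatives ran from 0.00117 to 0.067). The filaggrin relative Flg2 had 0.0436 ± 0.0708 against 50.7 ± 75.5 CPM (-10.37 ± 1.89, adjusted p = 0.00357). The cornified envelope protein Lce1m was lower by a ratio of 1970 (95% counting interval 673 to 9540) and the keratin Krt23 by 2110 (583 to 17400). Ratios of the same kind were 2410 (823 to 11700) for the sodium and proton exchanger Slc9a2 and 1950 (669 to 9480) for Fam110c. They were 3010 (835 to 24900) for the choline transporter relative Slc44a5 and 2320 (417 to 91700) for the natriuretic peptide Nppc. Adjusted p-values of these 6 genes ran from 0.00108 to 0.00504. The lectin Cd209b, with no count in GNA11 Q209L Bap1 KO, was at least 723-fold lower (adjusted p = 0.0136). Single libraries carry these ratios. Without BRAF V600E Bap1 KO replicate 4 they were 410 for Lce1m, 496 for Krt23, 1600 for Slc44a5 and a bound of 61.2 for Cd209b. Without BRAF V600E Bap1 KO replicate 1 they were 312 for Slc9a2, 827 for Fam110c and 407 for Nppc. Without GNA11 Q209L Bap1 KO replicate 5 they were 1120 for Lce1m, 1200 for Krt23, 1370 for Slc9a2, 1710 for Slc44a5, 1320 for Nppc and 3330 for Fam110c, and a bound of 411 for Cd209b. The ratio was 5110 for Lce1m and 5210 for Slc44a5 without GNA11 Q209L Bap1 KO replicate 2, and 5080 for Slc44a5 without replicate 4. Krt23 had a bound of 1180 without replicate 4 and Nppc of 667 without replicate 1, since no count was left. The Ras exchange factor Rasgrf1 had 0.029 ± 0.0480 against 94.2 ± 128 CPM (-11.47 ± 1.91, adjusted p = 0.002). Fitted changes moved with the setting. They were -5.63 for Rasgrf1 and -6.30 for Fam110c without BRAF V600E Bap1 KO replicates 1 and 2, and -5.90 for Flg2 and -6.31 for Lce1m without replicates 3 and 4. With limma voom they were -7.00 for Slc9a2 and -6.38 for Nppc. All 6 stayed past the threshold there. Without the library that carries it, the BRAF V600E Bap1 KO mean was 0.431 CPM for Crnn, 3.51 CPM for Wfdc12, 13.9 CPM for Flg2 (each without replicate 4) and 34.5 CPM for Rasgrf1 (without replicate 1). The GNA11 Q209L Bap1 KO mean was 0 for Wfdc12 and 0.0138 CPM for Flg2 without replicate 1, and 0.00864 CPM for Rasgrf1 without replicate 2. Amy1, a salivary amylase, had 1.62 ± 1.08 against 8730 ± 17450 CPM, with 34900 CPM in BRAF V600E Bap1 KO replicate 4. Its log2 fold change was -12.41 ± 3.03 (adjusted p = 0.0103), and -1.88 without that library (adjusted p = 0.0713). It was not called with limma voom either (-6.51, adjusted p = 0.109), nor without replicates 3 and 4 (-1.31, adjusted p = 0.226), where its alternatives ran from 0.00237 to 0.226.

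Among the key genes, Rasgrp3 was 80.3-fold higher in GNA11 Q209L Bap1 KO, at 643 ± 271 against 8.03 ± 5.58 CPM in BRAF V600E Bap1 KO (log2 6.33 ± 0.60, adjusted p = 0.000173). Mitf was 21.4-fold higher, at 719 ± 322 against 33.6 ± 8.02 CPM (4.42 ± 0.40, adjusted p = 0.000142). Plcb4 (255 ± 124 against 33.9 ± 43.8 CPM, 2.91 ± 0.86, adjusted p = 0.0217) and Kit (92.0 ± 106 against 16.5 ± 8.60 CPM, 2.48 ± 0.84, adjusted p = 0.036) were higher with groups that overlap. Plcb4 averaged 12.3 CPM without BRAF V600E Bap1 KO replicate 4 and Kit 46.0 CPM without GNA11 Q209L Bap1 KO replicate 3. Gnaq was higher at 131 ± 18.5 against 84.9 ± 6.71 CPM (adjusted p = 0.0151). Gna11 was higher at 320 ± 132 against 110 ± 52.9 CPM (adjusted p = 0.0199), although reads of the human GNA11 transgene may be counted there. The count of Bap1 was higher at 121 ± 29.7 against 60.9 ± 7.27 CPM (1.00 ± 0.23, adjusted p = 0.00811), although both genotypes are labelled as its knockout. Braf (44.8 ± 13.6 against 57.2 ± 12.96 CPM, adjusted p = 0.299), Prkcd (56.7 ± 9.03 against 72.5 ± 14.6 CPM, adjusted p = 0.41), Cdkn2a (15.2 ± 7.31 against 14.6 ± 17.8 CPM, adjusted p = 0.967) and Trp53 (104 ± 20.3 against 70.4 ± 33.0 CPM, adjusted p = 0.131) did not pass. The Cdkn2a mean was 7.07 CPM without BRAF V600E Bap1 KO replicate 3.

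**Figure D4:**
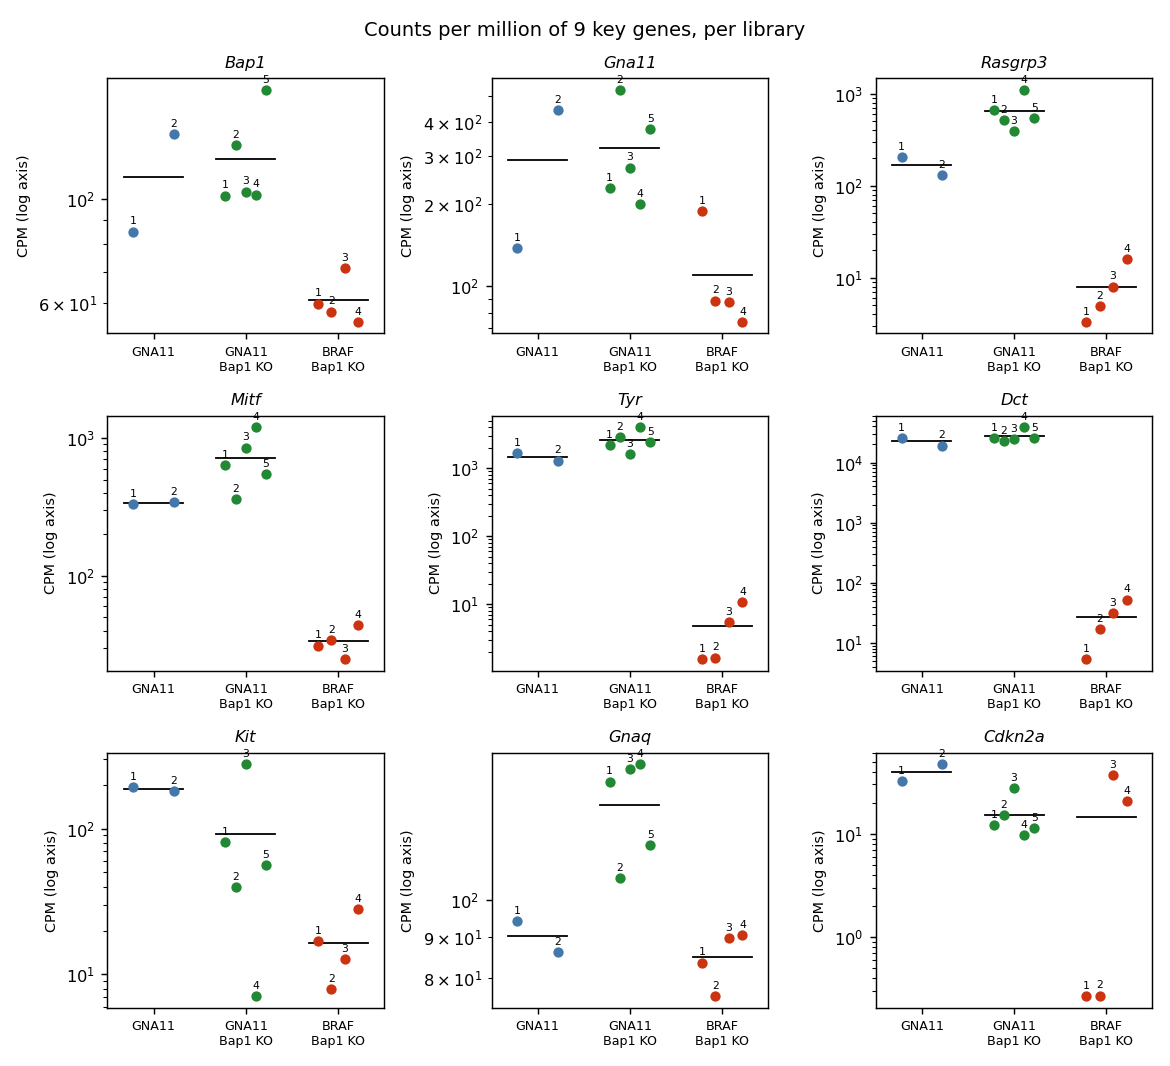
CPM on a log axis of the key genes in each library, coloured by genotype, with the mean as a black line. Tyr, Dct, Mitf and Rasgrp3 are high in all libraries with GNA11 Q209L and low in BRAF V600E Bap1 KO, while Bap1 stays between 54.7 and 170 CPM in every library.

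Pigment and energy genes were higher in GNA11 Q209L Bap1 KO than in BRAF V600E Bap1 KO. For list members, a value in parentheses without a unit is the log2 fold change, with its SE where given, and a value beside a left-out library is the camera adjusted p. Of the melanocyte lineage and pigment genes 19 of 22 rose (19 adjusted over the list alone), such as the pigment cell exchanger Slc24a5 (993 ± 204 against 4.43 ± 2.15 CPM). Their median log2 fold change was 7.66 (camera adjusted p = 2.04e-19, adjusted p = 0.181 with an estimated correlation). Of the oxidative phosphorylation genes 16 of 28 rose (17 adjusted over the list alone), among them Ndufa9 of complex I (1.41 ± 0.30) and Cox5b of cytochrome oxidase (1.08). Their median was 0.81 (camera adjusted p = 0.000338, adjusted p = 0.624 with an estimated correlation), and 1 was lower without GNA11 Q209L Bap1 KO replicate 4. Of the endothelial genes 3 of 17 rose (3 adjusted over the list alone), such as Vwf at 135 ± 16.1 against 30.2 ± 6.62 CPM. The endothelial median was 0.73 (camera adjusted p = 0.0232, adjusted p = 0.757 with an estimated correlation). There was no endothelial call without BRAF V600E Bap1 KO replicate 1 (0.0517), and 5 members with a median of 1.13 without replicate 3. Of the proliferation genes 6 of 26 rose (4 adjusted over the list alone), such as the replication licensing factor Mcm2 at 126 ± 58.5 against 29.3 ± 5.13 CPM (2.11 ± 0.40). The proliferation median was 0.52 (camera adjusted p = 0.0259, adjusted p = 0.757 with an estimated correlation). That call ended without GNA11 Q209L Bap1 KO replicate 1 (0.0792, with 1 lower) or BRAF V600E Bap1 KO replicate 3 (0.0537) or 4 (0.125), and the median was 0.86 without its replicate 2.

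Hypoxia and glycolysis genes were split between BRAF V600E Bap1 KO and GNA11 Q209L Bap1 KO, with 4 of 20 higher and 1 lower (3 and 1 adjusted over the list alone). The glycolytic enzymes Tpi1 (2.28) and Aldoa (2.39) were higher and the collagen hydroxylase P4ha2 (-1.31) lower. The median was 0.44 (camera adjusted p = 0.0466, adjusted p = 0.757 with an estimated correlation). This call ended without GNA11 Q209L Bap1 KO replicate 3 (0.0863), 4 (0.0564) or 5 (0.105, median 0.26). It also ended without BRAF V600E Bap1 KO replicate 2 (0.0553, median 0.28), 3 (0.148) or 4 (0.162). There were 3 higher and 0 lower without GNA11 Q209L Bap1 KO replicate 2, and 8 higher with a median of 0.89 without BRAF V600E Bap1 KO replicate 1.

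Genes of the skin and of muscle were lower in GNA11 Q209L Bap1 KO than in BRAF V600E Bap1 KO. Of the epidermal keratinocyte genes 11 of 20 fell (14 adjusted over the list alone), such as the basal keratin Krt15 (-8.94 ± 1.72). Their median was -5.06 (camera adjusted p = 1.05e-05, adjusted p = 0.757 with an estimated correlation). The keratinocyte mean in BRAF V600E Bap1 KO was 3.17, 4.53, 8.44 and 8.19 log2 CPM in replicates 1 to 4, and GNA11 Q209L Bap1 KO replicate 1 reached 4.65. Without that library 20 members were lower with a median of -9.75. Only 5 were without GNA11 Q209L Bap1 KO replicate 2, and 7 without its replicate 3 or 5 or BRAF V600E Bap1 KO replicate 3 or 4. Of the hair follicle genes 18 of 18 fell (18 adjusted over the list alone). Their median was -10.82, also with genes at no count set to their bound (camera adjusted p = 0.0219, adjusted p = 0.757 with an estimated correlation). They averaged -3.00, -3.07, 2.25 and 8.39 log2 CPM in BRAF V600E Bap1 KO replicates 1 to 4. Without replicate 3 (5 lower, camera adjusted p = 0.196) or 4 (3 lower, median -3.84, camera adjusted p = 0.233) they were not called. Fewer of the 18 genes pass the expression filter in these fits, so the values there cover a smaller set. Of the skeletal muscle genes 14 of 19 fell (15 adjusted over the list alone). Their median was -6.04 (camera adjusted p = 0.0274, adjusted p = 0.757 with an estimated correlation), and their mean 7.93 log2 CPM in BRAF V600E Bap1 KO replicate 4. Without that library 2 were lower and 1 higher, with a median of -1.97 and no call (camera adjusted p = 0.152). Without GNA11 Q209L Bap1 KO replicate 1, 2, 4 or 5 there were 8 lower.

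Genes of connective tissue and mast cells were lower in GNA11 Q209L Bap1 KO as well. Of the fibroblast and extracellular matrix genes 15 of 18 fell (16 adjusted over the list alone), such as the surface glycoprotein Thy1 at 21.3 ± 10.4 against 654 ± 389 CPM and Dcn at 25.7 ± 17.8 against 1148 ± 655 CPM. Their median was -3.01 (camera adjusted p = 0.000338, adjusted p = 0.757 with an estimated correlation). In the epithelial and mesenchymal switch 7 of 14 fell (7 adjusted over the list alone), among them the mesenchymal factor Twist1 (-6.38 ± 0.85) and the epithelial adhesion molecule Epcam (-6.90). This list had a median of -3.19 (camera adjusted p = 0.0292, adjusted p = 0.445 with an estimated correlation), with no call without GNA11 Q209L Bap1 KO replicate 2 (0.0553). Of the mast cell genes 10 of 11 fell (10 adjusted over the list alone), such as the mast cell carboxypeptidase Cpa3 at 0.428 ± 0.307 against 31.6 ± 28.3 CPM. The receptor Mrgprb1 alone was higher, at 976 ± 329 against 7.24 ± 5.17 CPM (1 adjusted over the list alone). Without BRAF V600E Bap1 KO replicate 1 the BRAF V600E Bap1 KO means were 17.8 CPM for Cpa3 and 4.76 CPM for Mrgprb1. The mast cell median was -6.20 (camera adjusted p = 0.000289, adjusted p = 0.616 with an estimated correlation).

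Lists of T and NK cell, neutrophil and macrophage genes were lower in GNA11 Q209L Bap1 KO than in BRAF V600E Bap1 KO. Of the T and NK cell genes 11 of 19 fell (13 adjusted over the list alone), such as the T cell surface protein Cd5 (-3.18) and the killer protease Gzmb (-4.21). Their median was -2.31 (camera adjusted p = 0.00335, adjusted p = 0.757 with an estimated correlation). That count was 6 without GNA11 Q209L Bap1 KO replicate 1, 3 or 4, 7 without replicate 2 or 5 and 2 without BRAF V600E Bap1 KO replicate 2. Of the neutrophil genes 3 of 11 fell (3 adjusted over the list alone), such as the decoy receptor Il1r2 (-5.19). The neutrophil median was -3.75 (camera adjusted p = 0.0219, adjusted p = 0.757 with an estimated correlation). There were 7 without GNA11 Q209L Bap1 KO replicate 1 and 6 without BRAF V600E Bap1 KO replicate 4, and the median was -2.46 without its replicate 2. Of the macrophage and myeloid genes 5 of 18 fell (5 adjusted over the list alone), such as the scavenger receptor Cd163 (-7.96 ± 1.30). The macrophage median was -1.83 (camera adjusted p = 0.0349, adjusted p = 0.757 with an estimated correlation). Their call ended without GNA11 Q209L Bap1 KO replicate 4 (0.0577) or 5 (0.0571) or BRAF V600E Bap1 KO replicate 1 (0.0747) or 2 (0.111). There were 3 lower without GNA11 Q209L Bap1 KO replicate 1 or 3 or BRAF V600E Bap1 KO replicate 2, and 1 higher without GNA11 Q209L Bap1 KO replicate 4.

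Of all 17350 genes 7146 passed between BRAF V600E Bap1 KO and GNA11 Q209L Bap1 KO (2865 higher and 4281 lower in the latter). Beside that share, members of signalling and lineage lists moved, but the lists did not pass with camera. With fry 3 of them passed, each lower in GNA11 Q209L Bap1 KO: YAP and TEAD targets (adjusted p = 0.000387), neural crest and dedifferentiated melanoma (0.0157) and Schwann cell genes (0.0392). In Gq and RasGRP signalling 5 of 22 rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.883). The kinase gene Prkce was higher (1.77 ± 0.33) and the Ras exchange factor Rasgrp1 lower (-4.67 ± 0.63). There were 3 higher without BRAF V600E Bap1 KO replicate 2. In MAPK pathway output 3 of 20 rose and 7 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.547), with the transcription factor Etv1 at 4.96 ± 2.19 against 78.4 ± 53.0 CPM. Without BRAF V600E Bap1 KO replicate 1 there were 6 higher. Among YAP and TEAD targets 1 of 22 rose and 9 fell (3 and 12 adjusted over the list alone, camera adjusted p = 0.113), with Axl at 44.4 ± 17.2 against 678 ± 394 CPM. There were 2 higher without GNA11 Q209L Bap1 KO replicate 2 or 3 and 3 without BRAF V600E Bap1 KO replicate 1. Of the neural crest and dedifferentiated melanoma genes 8 of 16 fell (8 adjusted over the list alone, camera adjusted p = 0.113), such as the stem cell factor Sox2 (-9.20 ± 1.13). The list was called without BRAF V600E Bap1 KO replicate 2 (0.0424, with 1 higher). Of the Schwann cell genes 6 of 13 fell (7 adjusted over the list alone, camera adjusted p = 0.099), with calls without BRAF V600E Bap1 KO replicate 1 (0.0296) or 2 (0.0432) and 1 higher without its replicate 3. Of the Bap1 complex partners 4 of 20 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.868), with the DNA repair gene Brca1 at 149 ± 49.3 against 12.4 ± 4.23 CPM. These were 2 and 2 without GNA11 Q209L Bap1 KO replicate 2 or 5 or BRAF V600E Bap1 KO replicate 2, and 2 and 3 without its replicate 3. Of the Hox genes 2 of 26 rose and 8 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.549). Without GNA11 Q209L Bap1 KO replicate 2 or 5 or BRAF V600E Bap1 KO replicate 2 or 4 there were 0 higher and 4 or 5 lower. There were also 0 higher without GNA11 Q209L Bap1 KO replicate 1 or BRAF V600E Bap1 KO replicate 3, and 5 lower without GNA11 Q209L Bap1 KO replicate 3. Of the uveal melanoma class 2 low genes 1 of 8 rose and 2 fell (1 and 3 adjusted over the list alone), and of the class 2 high genes 0 of 4 changed (0 adjusted over the list alone). Both had camera adjusted p = 0.868. Class 2 low genes had 1 lower without GNA11 Q209L Bap1 KO replicate 2, 3, 4 or 5 or BRAF V600E Bap1 KO replicate 3 or 4. Class 2 high genes had 1 higher without BRAF V600E Bap1 KO replicate 1 and 1 lower without its replicate 4.

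The remaining lists did not pass with camera in this comparison either, and with fry the immediate early and heat shock genes passed (lower, adjusted p = 0.0348). Hair follicle (fry adjusted p = 0.177), skeletal muscle (0.177), macrophage (0.111), proliferation (0.265) and hypoxia genes (0.254), called by camera, did not pass with fry. Of the adipocyte genes 10 of 15 fell (10 adjusted over the list alone, camera adjusted p = 0.182), with a call without BRAF V600E Bap1 KO replicate 1 (0.0275). There were 4 to 6 lower without BRAF V600E Bap1 KO replicate 4 or GNA11 Q209L Bap1 KO replicate 1, 2, 3 or 5, and 1 higher without its replicate 4. Of the B and plasma cell genes 4 of 8 fell (4 adjusted over the list alone, camera adjusted p = 0.2), but 2 without GNA11 Q209L Bap1 KO replicate 2, 3 or 5 and 1 without BRAF V600E Bap1 KO replicate 2. Of the immediate early and heat shock genes 1 of 14 rose and 6 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.272), such as Egr1 (-1.38). There were 4 and 3 lower and 0 higher without GNA11 Q209L Bap1 KO replicate 2 and 5, and 0 higher without BRAF V600E Bap1 KO replicate 1, 2 or 4. Of the antigen presentation genes 1 of 17 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.805). There were 2 lower without GNA11 Q209L Bap1 KO replicate 1, and 1 without its replicate 3, 4 or 5, with 2 higher without replicate 4. Without BRAF V600E Bap1 KO replicate 1, 2 and 4 there were 8, 1 and 2 lower and 1, 4 and 0 higher. Of the interferon response genes 1 of 23 rose and 4 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.868). Without GNA11 Q209L Bap1 KO replicate 2, 3 and 5 there were 0, 1 and 3 higher and 3, 2 and 2 lower. Without BRAF V600E Bap1 KO replicate 1, 2 and 3 there were 0, 2 and 0 higher and 4, 0 and 5 lower. Of the red blood cell genes 0 of 7 changed (0 adjusted over the list alone, camera adjusted p = 0.868), and 1 was lower without GNA11 Q209L Bap1 KO replicate 5.

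GNA11 Q209L tumours also carried far more pigment transcripts than BRAF V600E Bap1 KO tumours. The largest rises were those of Pmel (log2 10.51 ± 1.01, adjusted p = 0.000431), Kcnj13 (10.47 ± 0.83), Cort (10.18 ± 0.80), Tspan10 (9.84 ± 0.64) and Slc45a2 (9.84 ± 0.79). Of the melanocyte lineage and pigment genes 18 of 22 rose (20 adjusted over the list alone). Their median was 7.83 (camera adjusted p = 9.24e-24, adjusted p = 0.104 with an estimated correlation). Genes with no count in GNA11 Q209L were Fam25c, Slc9a2, Flg2, Slc44a5 and Krt23, and their folds are lower bounds. Fam25c was at least 1230-fold lower (adjusted p = 0.0377), Slc9a2 at least 1090-fold (0.0402), Flg2 at least 1030-fold (0.0339), Slc44a5 at least 911-fold (0.046) and Krt23 at least 637-fold (0.019). In the same order the bounds were 456, 403, 379, 337 and 235 without GNA11 Q209L replicate 1 and 777, 687, 646, 574 and 401 without replicate 2. They were 804 for Fam25c without BRAF V600E Bap1 KO replicate 3, 142 for Slc9a2 without its replicate 1, and 281 for Flg2, 484 for Slc44a5 and 150 for Krt23 without its replicate 4. None of these 5 calls held without GNA11 Q209L replicate 1 (adjusted p = 0.0774 to 0.146) or 2 (0.134 to 0.248), with limma voom (0.0823 to 0.325) or with only the libraries of the 2 genotypes (0.0816 to 0.152). With the Xist covariate the calls of Fam25c (0.067), Flg2 (0.0624) and Slc44a5 (0.0792) ended, and with the libraries that share an identifier summed those of Slc9a2 (0.0516) and Slc44a5 (0.0564). Fam25c and Slc44a5 also ended without BRAF V600E Bap1 KO replicate 3 (0.0509 and 0.0613), and Slc44a5 without replicate 4 (0.0566). Rasgrp3 (4.39 ± 0.59, adjusted p = 0.00257), Mitf (3.33, adjusted p = 0.00201) and Kit (3.50 ± 0.98, adjusted p = 0.0389) were higher in GNA11 Q209L. Bap1 did not pass (0.87 ± 0.28, adjusted p = 0.0601).

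Of 17350 genes 2637 passed between GNA11 Q209L and BRAF V600E Bap1 KO, 1609 higher and 1028 lower in GNA11 Q209L. At least a 2-fold change was found in 2547. The groups did not overlap in 41.9% of genes, where chance gives 13.33%. The count was 1078 without GNA11 Q209L replicate 1, 265 without replicate 2 and 1737 without BRAF V600E Bap1 KO replicate 2. Of the oxidative phosphorylation genes 12 of 28 rose (17 adjusted over the list alone), but 5 and 0 without GNA11 Q209L replicate 1 and 2. Their median was 1.08 (camera adjusted p = 1.33e-05, adjusted p = 0.6 with an estimated correlation). Of the mast cell genes 7 of 11 fell and 1 rose (8 and 1 adjusted over the list alone). Their median was -5.31 (camera adjusted p = 3.93e-05, adjusted p = 0.6 with an estimated correlation). Without GNA11 Q209L replicate 1 there were 4 lower (median -8.41), and without replicate 2 there were 0. Of the epidermal keratinocyte genes 4 of 20 fell (16 adjusted over the list alone). Their median was -9.68, or -9.38 with genes at no count set to their bound (camera adjusted p = 1.07e-07, adjusted p = 0.805 with an estimated correlation). There were 0 lower without GNA11 Q209L replicate 1 or 2, 7 without BRAF V600E Bap1 KO replicate 1, and 1 and 2 without its replicates 3 and 4.

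Proliferation genes were lower in GNA11 Q209L than in BRAF V600E Bap1 KO in 4 of 26 (4 adjusted over the list alone). Their median was -1.01 (camera adjusted p = 0.00218, adjusted p = 0.805 with an estimated correlation). Without GNA11 Q209L replicate 1 there was 1, with a median of -0.57 and no call (0.295), and without replicate 2 there were 0 with a median of -1.68. Of the endothelial genes 2 of 17 rose (8 adjusted over the list alone). The endothelial median was 1.38 (camera adjusted p = 0.000152, adjusted p = 0.655 with an estimated correlation). There was 1 without GNA11 Q209L replicate 1 (median 0.78) or 2 or BRAF V600E Bap1 KO replicate 2, and 4 without its replicate 3. Of the hypoxia and glycolysis genes 4 of 20 rose (4 adjusted over the list alone). The hypoxia median was 1.07 (camera adjusted p = 0.0333, adjusted p = 0.805 with an estimated correlation). It was -0.04 without GNA11 Q209L replicate 2 (0 called, 0.755) and 1.64 without replicate 1. There was no hypoxia call without BRAF V600E Bap1 KO replicate 3 (0.107, with 2 genes) or 4 (0.0934), and 1 gene without its replicate 2. Skeletal muscle genes had a median of -8.33 (camera adjusted p = 0.00245, adjusted p = 0.805 with an estimated correlation), with 0 called over all genes and 11 lower adjusted over the list alone. Hair follicle genes had -10.08, or -10.0 with genes at no count set to their bound (camera adjusted p = 0.0402, adjusted p = 0.805 with an estimated correlation), with 0 called and 16 lower adjusted over the list alone. The muscle median was -3.85 without BRAF V600E Bap1 KO replicate 4, and 4, 2 and 1 muscle genes were lower without its replicates 1, 3 and 4. Without replicates 1 and 2 there were 2 and 1 hair follicle genes lower. Without BRAF V600E Bap1 KO replicate 3 or 4 fewer hair follicle genes pass the expression filter, so the values there cover a smaller set. Hair follicle genes were not called without GNA11 Q209L replicate 1 (0.136) or BRAF V600E Bap1 KO replicate 3 (0.322) or 4 (0.476, median -3.59).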

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

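The tests of fewer tumour cells, sex, a few abundant genes, skin tissue, salivary tissue and read carry-over, and the splits for the lists of GNA11 Q209L Bap1 KO against GNA11 Q209L, were chosen only after the result was seen.

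Gene and list counts were set against other splits of the same libraries. For GNA11 Q209L Bap1 KO against GNA11 Q209L, 1 of the 21 splits of the 7 libraries, the real one, gave as many as 5 genes, and the highest of the others gave 3. These splits take the 2 libraries that share an identifier as independent. Counted as 1 unit they leave 15 splits, too few for a share under 0.05, and with them summed edgeR called 0 genes (1743 at an unadjusted p under 0.05, and no other tool was run on the sum). For the number of lists called in this comparison chance cannot be excluded, since 10 of 21 splits gave 9 or more lists and the highest of the others gave 15. Against BRAF V600E Bap1 KO, 1 of 100 splits drawn from the 126 of the 9 libraries, the real one, gave as many as 7146 genes. The highest of the others gave 0 with edgeR. Chance is argued against, although with the libraries that share an identifier as 1 unit there are 35 splits. Mixed splits also add the difference between the genotypes to the spread within groups, which makes calls in them harder. For the number of lists called in that comparison chance cannot be excluded, since 13 of 100 splits gave 14 or more lists and the highest of the others gave 18. That number does not bear on any single list. Pigment list means, for example, did not overlap (9.63 to 9.95 in GNA11 Q209L Bap1 KO against 1.61 to 3.81 log2 CPM).

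Higher proliferation genes in GNA11 Q209L Bap1 KO than in GNA11 Q209L were weighed first. The median of 1.63 was reached by 1 of 21 splits, the real one, but with the libraries that share an identifier as 1 unit the 15 splits are too few for a share under 0.05, and the highest of the others gave 1.6 and set GNA11 Q209L replicate 1 and GNA11 Q209L Bap1 KO replicate 3 against the rest. Fewer tumour cells in the GNA11 Q209L samples are argued against as the whole cause only if pigment genes measure tumour cells. Proliferation minus pigment list mean was higher by 1.5 log2 units in GNA11 Q209L Bap1 KO (SD 0.56, n = 5). The values were -6.58 and -5.84 against -5.62 to -4.11. CreERT2 stood lower in GNA11 Q209L (85.6 and 129 against 181 to 326 CPM), but the human GNA11-Q209L and EGFP sequences stood higher. Fewer tumour cells therefore stay open as a cause. Fibroblast genes stood higher in GNA11 Q209L (median -2.31, and -1.04 without its replicate 1). Macrophage (-1.86) and endothelial medians (-0.70) rest on that replicate and were 0.16 and -0.03 without it. Sex of the mice could account for part of the proliferation difference and stays open, because both GNA11 Q209L libraries and 1 of 5 GNA11 Q209L Bap1 KO libraries were above 50 CPM of Xist, and with an Xist covariate the proliferation median was 0.97 instead of 1.63. The same libraries had the FLP recombinase sequence at 0.0541 CPM or less, against 36.44 to 154.3 CPM in the other GNA11 Q209L Bap1 KO libraries. The covariate therefore cannot part sex from whatever that sequence marks. The labelled Bap1 knockout stays open as an untested biological explanation, since the Bap1 count does not show it (121 against 111 CPM, adjusted p = 0.92) and sex is not balanced. The human GNA11-Q209L sequence stood at 23.0 and 125 CPM in GNA11 Q209L and from 6.52 to 17.4 CPM in GNA11 Q209L Bap1 KO. Its level cannot be parted from the label either.

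Lower pigment genes in BRAF V600E Bap1 KO than in GNA11 Q209L Bap1 KO were weighed next. A few abundant genes in BRAF V600E Bap1 KO replicate 4, where 10 genes took 21.9% of the counts, are argued against by the other libraries. In replicates 1 to 3 the 10 most abundant genes took 5.1%, 3.7% and 6.1%. Their pigment means of 1.61, 2.41 and 3.33 log2 CPM lay below the 3.81 of replicate 4. Leaving out the library with the highest pigment mean could hardly lower the median (8.29 without it, 7.66 with it), so that test decides nothing by itself. Skin tissue in place of tumour and an oncogene effect cannot be told apart in BRAF V600E Bap1 KO replicates 1 and 2, with pigment means of at most 2.41 log2 CPM. Their keratinocyte means of 3.17 and 4.53 were no higher than the 4.65 of GNA11 Q209L Bap1 KO replicate 1, which had a pigment mean of 9.68, but that is a single library, and their fibroblast means of 7.78 and 7.30 decide nothing, lying above the 4.11 to 6.35 of GNA11 Q209L Bap1 KO but below the 8.19 of GNA11 Q209L replicate 1 with its pigment mean of 9.68. The hair follicle means of replicates 1 and 2 (-3.00 and -3.07) lay within the -3.53 to -2.41 of the libraries with GNA11 Q209L. In replicates 3 and 4 they were 2.25 and 8.39. Hair follicle genes thus gave no sign of skin in replicates 1 and 2, which does not exclude skin without them. In replicates 3 and 4, with pigment means of at most 3.81 and keratinocyte means of 8.44 and 8.19, skin tissue and an oncogene effect cannot be told apart either, because no library with GNA11 Q209L held as much keratinocyte RNA.

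Salivary genes in BRAF V600E Bap1 KO replicate 4, with Bpifa2 at 98000, Smr3a at 40680, Amy1 at 34900 and Chia at 9828 CPM, were weighed last. On a list of 28 salivary gland genes, of which 19 had a count, 17 were highest in that library, and 16 of 18 without Dcpp1, which is also 1 of the 7 leading genes (exact one-sided binomial p = 2.83e-16 for the 17 against 1 in 11, which takes genes expressed together as independent). A candidate source is therefore salivary gland tissue in the sample, and no biological explanation was tested. In GNA11 Q209L replicate 2 the 7 leading salivary genes stood at 230 ppm of their level in that library (95% counting interval 216 to 245), for example Bpifa2 at 25.86 CPM, against 2.98 to 22.3 ppm in the 6 other libraries with GNA11 Q209L. Whether this is carry-over of reads cannot be told: hair follicle genes abundant in the same BRAF V600E Bap1 KO library stood at 165 ppm (107 to 244), but also at 178 ppm in GNA11 Q209L replicate 1 and 217 ppm in GNA11 Q209L Bap1 KO replicate 1.

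Single libraries far from the others of their genotype were found in 22 of 156 groups of values, where chance gives about 1 in 20. The value that measures this is the gap to the nearest other library divided by the whole range, both on the log2 scale, with 0.1 CPM added for genes and transgene sequences. Among genes, Dct in GNA11 Q209L Bap1 KO replicate 4 (38840 CPM, others 22820 to 25890) had 0.762, and Dpysl3 in its replicate 5 (4.667, others 14.6 to 18.13) had 0.839. In BRAF V600E Bap1 KO, Cited1 had 0.888 in replicate 2 (1.261, others 0.3935 to 0.4527), Pmel 0.881 in replicate 1 (3.663, others 20.58 to 25.93) and Amy1 0.887 in replicate 4 (34900, others 3.416 to 9.82). Wfdc12 (0.2715 CPM) and Nppc (0.05429 CPM) in GNA11 Q209L Bap1 KO replicate 1, Slc9a2 (0.1623 CPM) in replicate 3 and Krt23 (0.09522 CPM) in replicate 4 each had 1, because the other libraries had 0 counts.

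Among list means in GNA11 Q209L Bap1 KO, epidermal keratinocyte genes had 0.761 in replicate 1 (4.65 log2 CPM, others -2.56 to -0.84). Bap1 complex partners had 0.889 in replicate 2 (5.08, others 5.40 to 5.44) and Gq and RasGRP signalling 0.714 in replicate 5 (4.15, others 4.50 to 4.64). In replicate 3, Hox genes had 0.725 (-3.44, others -1.83 to -1.22) and immediate early and heat shock genes 0.714 (5.08, others 4.10 to 4.38). In BRAF V600E Bap1 KO, mast cell genes had 0.853 in replicate 1 (4.53, others 2.56 to 2.85). In its replicate 2, YAP and TEAD targets had 0.833 (5.11, others 5.51 to 5.59) and uveal melanoma class 2 high genes 0.921 (4.78, others 5.36 to 5.41).

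The human BRAF exon 15-18 sequence had 1 in GNA11 Q209L Bap1 KO replicate 1, from a single count of 0.05429 CPM. The FLP recombinase sequence had 0.791 in GNA11 Q209L Bap1 KO replicate 3 (0.0541 CPM, others 36.44 to 154.3) and 0.854 in BRAF V600E Bap1 KO replicate 3 (0.4179 CPM, others 74.37 to 174.3). Total counts had 0.844 in GNA11 Q209L Bap1 KO replicate 5 and 0.964 in BRAF V600E Bap1 KO replicate 1. These libraries had about 69712200 counts (others about 18338100 to 22584700) and about 81035100 counts (others about 21539600 to 22579000). Outside the tests of mouse genes, the FLP recombinase reached 174 CPM in BRAF V600E Bap1 KO replicate 4 and the neomycin resistance sequence 16.8 CPM in BRAF V600E Bap1 KO replicate 2.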

How the results depend on the processing

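Fits without genes on X and Y, with an Xist covariate or without a pair of BRAF V600E Bap1 KO libraries were chosen after the data were seen, and where a value moved the cause was not tested. For GNA11 Q209L Bap1 KO against GNA11 Q209L the 5 genes became 3 with RLE size factors, 3 with no filter, 8 with a stricter filter, 442 with DESeq2, 16 with limma voom and 64 with only the 2 genotypes. All 5 are among those of DESeq2 and of the 2 genotypes alone, and 4 among those of limma voom. The count was 2 without genes on chromosomes X and Y, 46 and 63 without BRAF V600E Bap1 KO replicates 1 and 2 or 3 and 4, and 0 to 1 without a single library. It was 0 with the libraries that share an identifier summed (1743 genes at an unadjusted p under 0.05) and 0 with the Xist covariate (1309). In place of its 9 lists, 0 were called by camera with an estimated correlation, 0 by fry, and 4 to 14 without a single library, of which 3 to 9 are among the 9. Camera called 12 lists with only the 2 genotypes and 14 with the Xist covariate, each including the 9. For GNA11 Q209L Bap1 KO against BRAF V600E Bap1 KO the number of genes stayed within 1.5 times 7146 in every setting, the lowest being 5072 without BRAF V600E Bap1 KO replicates 3 and 4, of which 4139 are shared. In place of its 14 lists there were 0 with an estimated correlation and 13 with fry, of which 9 are among the 14. For GNA11 Q209L against BRAF V600E Bap1 KO the 2637 genes became 5458 with DESeq2, 1470 with limma voom, 417 with only the 2 genotypes, 1168 with the Xist covariate and 265 to 2867 without a single library. In place of its 9 lists there were 0 with an estimated correlation and 7 with fry, of which 5 are among the 9. Of the values of named genes under the alternatives, 43 of 94, 469 of 480 and 147 of 175 in the 3 comparisons stayed past the threshold, the rest fell below it and 0 reversed. Another 30 gave no value because the gene was filtered out. Leaving out a GNA11 Q209L library leaves a lone sample, which is assumed to vary like the other groups. No paired analysis was possible because replicate numbers follow accession order and the labels name no pairs. Depth limits genes with few counts: 3 counts are up to 0.166 CPM in a library.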

Other observations

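With the fit of the GNA11 Q209L and GNA11 Q209L Bap1 KO libraries alone, 64 genes passed, and the genes named here were chosen after their values were seen. Kcnj10, a potassium channel of glia and melanocytes, stood at 0.389 ± 0.376 CPM (SD, n = 5) in GNA11 Q209L Bap1 KO against 46.4 ± 16.1 CPM (SD, n = 2) in GNA11 Q209L (log2 fold change -6.92, adjusted p = 0.0274). Epas1, a hypoxia-inducible transcription factor, stood at 105 ± 29.6 against 611 ± 122 CPM (-2.55, adjusted p = 0.0274). Efemp1, an extracellular matrix protein, stood at 4.61 ± 0.868 against 38.9 ± 3.14 CPM (-3.08, adjusted p = 0.0206). Rap1gap, which switches off the small G protein Rap1, stood at 51.0 ± 20.6 against 2.43 ± 0.785 CPM (4.40, adjusted p = 0.0313), and the receptor phosphatase Ptprf at 182 ± 45.7 against 19.3 ± 3.41 CPM (3.23, adjusted p = 0.0274). None of these 5 passed with all 11 libraries, where adjusted p ran from 0.133 to 0.164. In the 20 other splits of the 7 libraries this fit called 0 genes. With the libraries that share an identifier as 1 unit the 15 splits are too few for a share under 0.05. Xist levels nearly follow the grouping as well, so the splits cannot part the labelled knockout from sex.

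The 4 BRAF V600E Bap1 KO tumours differed in the lineage genes they carried, and no test was run between them. Sox10, a transcription factor of neural crest, melanocytes and Schwann cells, stood at 1.93, 3.58, 533 and 232 CPM in replicates 1 to 4. The receptor gene Erbb3 stood at 2.85, 11.4, 698.5 and 296 CPM and the adhesion gene Cdh19 at 0.539, 5.56, 447 and 172 CPM. The other way round, the interleukin 33 receptor gene Il1rl1 stood at 2325, 2374, 12.5 and 8.48 CPM, Pdgfra, a receptor of mesenchymal cells, at 1181, 764, 145 and 101.5 CPM, and the bone matrix gene Dmp1 at 636, 145.5, 1.39 and 0.743 CPM. Cdkn2a stood at 0.27, 0.27, 37.1 and 20.7 CPM in the same order.

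Xist stood at 358 and 198 CPM in GNA11 Q209L. In GNA11 Q209L Bap1 KO it stood at 695 CPM in replicate 3 and from 0.428 to 1.42 CPM in the others. In BRAF V600E Bap1 KO it stood at 99.8 and 1224 CPM in replicates 1 and 3 and under 1 CPM in replicates 2 and 4. The Y-linked gene Ddx3y had 0 counts in both GNA11 Q209L libraries and in GNA11 Q209L Bap1 KO replicate 3. It stood at 9.99, 1.27, 18.3 and 5.72 CPM in GNA11 Q209L Bap1 KO replicates 1, 2, 4 and 5, and at 135 and 59.9 CPM in BRAF V600E Bap1 KO replicates 2 and 4. The FLP recombinase sequence was near 0 in the same GNA11 Q209L libraries, in GNA11 Q209L Bap1 KO replicate 3 and in BRAF V600E Bap1 KO replicate 3, and above 36 CPM in the other 7 libraries.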
